A study of Populus ussuriensis with 12 samples.

How the data were processed

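RNA was sequenced from roots of *Populus ussuriensis*, a poplar, grown in vitro. Per the labels, the plants were wild type or overexpressed PuC3H35, were 7 days old at transfer, and then spent 7 days on control medium or on medium with 6% PEG6000. PEG6000 is polyethylene glycol of mean molecular weight 6000, which lowers the water potential of the medium and is used to impose drought-like stress. Total RNA was extracted with a CTAB method and libraries were made with an Illumina TruSeq kit, per the labels' protocols. There were 12 libraries in 4 groups of 3. Groups were taken from the tissue label of each library.

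Each deposited file held 1 value for each of 35907 gene identifiers in 1 library, and the unit was not named by its header. The values were FPKM (fragments or reads per kilobase of gene, scaled to the library total), as judged from the deposited values themselves: once each file was multiplied by 1 factor for its depth, a gene's values were whole multiples of 1 step, as whole reads divided by a gene length and a library total would be. Reads and fragments, and so RPKM and FPKM, could not be told apart this way, and FPKM is used as the name throughout. Bowtie2 2.2.3 and HISAT2 2.1.0 are named in the submitters' processing notes without their roles. The counting tool, the gene annotation and the genome build are not given in the sources used here. The gene identifiers are printed exactly as the files give them. The files pair 0 identifiers with a gene name or a product description, so 28 gene lists fixed in advance (among them lignin, proanthocyanidin, abscisic acid and dehydrin genes) were not tested, and the level of PuC3H35 itself was not checked.

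Whole reads were recovered from the FPKM steps. Of 370737 values above 0, 100.0% came out whole within 0.01 read, and 99.99% of the 11302 gene lengths checked were whole within 0.002 bases. On simulated libraries 99.91% of 4617 genes were recovered exactly. Recovered totals ran from 10566326 to 12053123 reads per library. These reads served to describe depth and for an added alternative test, and the main test used FPKM. A count model had been planned in case the files held counts, and the test planned for normalized values was used because they did not.

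The main test was limma 3.58.1 (empirical Bayes with an intensity trend) in R 4.3.3 on log2(FPKM + 1). It ran over 24976 genes with at least 1 FPKM in 3 or more libraries, as 1 fit of 4 group means to all 12 libraries with 8 residual degrees of freedom. Adjusted p is the Benjamini-Hochberg value over these genes, and a gene is called changed, higher or lower when it is under 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of genes with low values. A log2 value of 1 is a 2-fold and of 2 a 4-fold change. Tests were two-sided. No factor between libraries was applied beyond the authors' FPKM. Genotypes were compared on each medium, media within each genotype, and the difference of the media effects between genotypes as an interaction. Standard errors (SE) are the moderated ones of limma, and SD is over 3 libraries. The labels do not say that the libraries came from separate plants or lines, so p-values measure the spread between these libraries, which may in part be technical. The effects of the overexpressed gene and of the transgenic material that carries it are not separated by this design.

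In simulated data for the genotype comparison on control medium (24556 genes), limma called 17.9% of genes changed 1.5-fold, 61.2% of genes changed 2-fold and 93.8% of genes changed 4-fold in the right direction, and called 4 of 24357 unchanged genes. These shares hold for few changed genes (118 calls), where the adjusted p is stricter than in the data, where many more genes were called. Named genes were chosen by a rule set before the data were examined. For each comparison it takes the 2 genes with the largest rise and the 2 with the largest fall among called genes with a mean of at least 5 FPKM in the higher group and no overlap between the groups' libraries. For the interaction, the groups without overlap are both genotypes on PEG, and the minimum mean was applied to the highest of the 4 groups.

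The size of the overexpressor's PEG response was expressed as a slope over genes on the wild-type response, with the variance that the spread between libraries adds to the wild-type response subtracted and a jackknife SE over the 12 libraries. Slopes of the genotype effects were also corrected for the wild-type libraries they share with the PEG response. For comparisons that share libraries, 20 simulations of unchanged groups gave the chance correlation and covariance. Replicate numbers match across the wild-type groups (1, 2 and 3) but not across the overexpressor groups (1, 2 and 5, and 1, 3 and 4). No label gives the numbers a meaning and same-numbered libraries did not as a rule deviate together, so the libraries were not paired. Whether the numbers mark transgenic lines cannot be told. The PEG comparison in the overexpressor may therefore in part compare different lines. The alternatives tried were a pseudocount of 0.1, no filter, a mean of at least 5 FPKM, a fold change threshold, a replicate block, fits of 6 libraries, other scalings between libraries, limma-voom on recovered reads, and each library left out in turn. Computation also used NumPy 2.4.6 and pandas 2.3.3, and plots were drawn with Matplotlib 3.10.9.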

Results

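Root transcriptomes of wild-type *P. ussuriensis* and of a PuC3H35 overexpressor were compared after 7 days on control medium or on 6% PEG6000. PuC3H35 is a member of the C3H (CCCH) zinc finger protein family. The design asks how overexpression changes root gene expression, how roots respond to PEG, and whether that response differs between the genotypes. Each of the 4 groups had 3 libraries. Recovered depth ran from 10566326 reads (wild type on PEG, library 1) to 12053123 reads (wild type on control medium, library 3), and each library had at least 1 read for 30432 to 31610 of 35907 genes. The 10 most abundant genes took 5.55% to 7.16% of the summed FPKM. Replicate libraries differed by more than sampling noise in every group, with a chi-square of 3.23 to 17.15 per gene over pairs, so no pair agreed within sampling noise. Across genes, which are not independent replicates, replicate pairs had Pearson correlations of 0.983 to 0.993.

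Genotype and medium both separated the libraries. The first principal component, with 47.2% of the variance, placed wild type on control medium at one end and wild type on PEG at the other, with the overexpressor libraries between them. On this component the overexpressor controls lay on the control side and the overexpressor PEG libraries on the PEG side. The second component (21% of the variance) set the genotypes apart. The third component (9%) spread libraries within groups, and its extremes were library 4 of the overexpressor on PEG and library 2 of the overexpressor controls.

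**Figure D1:**
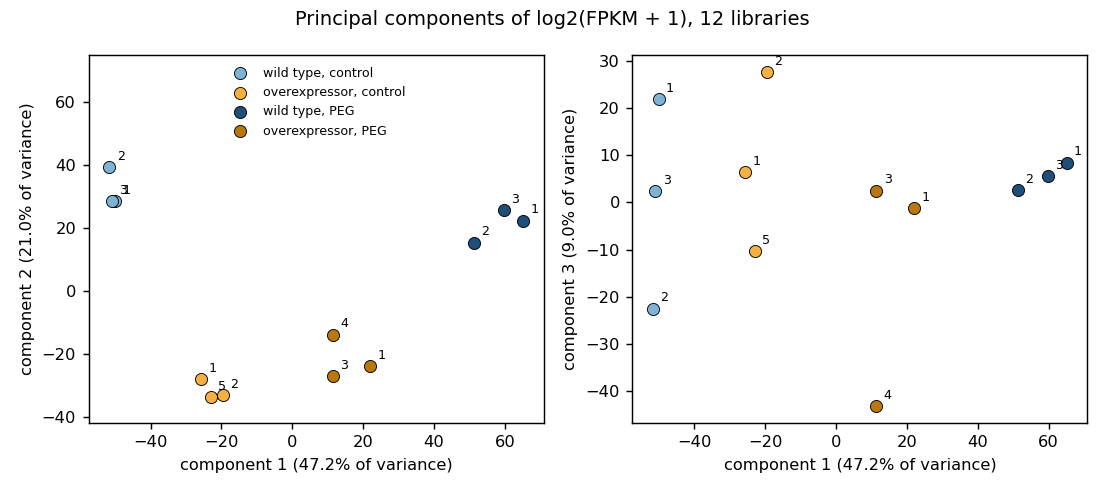
Principal component scores of the 12 libraries from log2(FPKM + 1). Each point is a library with its replicate number, and colours mark the 4 groups. Component 1 (47.2% of the variance) separates the media more widely in wild type than in the overexpressor, and component 2 (21%) separates the genotypes.

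PEG changed a large part of the wild-type root transcriptome: 2994 genes were higher and 4153 lower on PEG, of 24976 tested. Large changes were mostly rises, with 427 genes at least 4-fold higher against 123 at least 4-fold lower. The excess of lower over higher genes depends on the scaling, since median-ratio scaling gave 3536 higher and 3538 lower and limma-voom 3468 and 3446. The largest rises were in Potri.001G391200.v3.1, from 0.622 ± 0.283 FPKM on control medium to 629 ± 217 on PEG (SD, n = 3), and Potri.007G120400.v3.1, from 1.89 ± 0.395 to 1045 ± 292 FPKM. Their log2 changes were 8.54 (SE 0.416) and 8.47 (SE 0.36), with adjusted p of 9.53e-08 and 4.36e-08. The largest falls were in Potri.014G149700.v3.1, from 120 ± 35.5 to 2.31 ± 0.997 FPKM, and Potri.001G176200.v3.1, from 110 ± 52.9 to 3.32 ± 2.47 FPKM. These changed by -5.21 (SE 0.366, adjusted p 1.36e-06) and -4.72 (SE 0.438, adjusted p 1.11e-05) on the log2 scale. A further group of 58 genes was under 1 FPKM in all 3 wild-type controls and at 10 FPKM or more in all 3 wild-type PEG libraries, with medians over genes of 0.215 and 29 FPKM. Over all tested genes, 44.3% had no overlap between the 3 libraries on each medium, where chance gives 10%.

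The overexpressor responded to PEG with far fewer called genes, 385 higher and 134 lower. Rises again outnumbered falls among large changes, with 79 genes at least 4-fold higher. Potri.012G006800.v3.1 rose most, from 2.5 ± 2.16 to 89.5 ± 8.45 FPKM (log2 change 4.87, SE 0.459, adjusted p 2.17e-04), followed by Potri.007G120400.v3.1, from 1.33 ± 0.411 to 59.8 ± 41.2 FPKM (log2 change 4.52, SE 0.36, adjusted p 7.13e-05). Both also rose in wild type, to 452 ± 59.3 and 1045 ± 292 FPKM. The largest falls were in Potri.007G086400.v3.1, from 15 ± 6.97 to 1.25 ± 0.174 FPKM, and Potri.001G235500.v3.1, from 47.9 ± 4.8 to 11.2 ± 4.2 FPKM. Their log2 changes were -2.75 (SE 0.365, adjusted p 0.00209) and -2.06 (SE 0.337, adjusted p 0.00771), and in wild type these genes changed by -2.48 and -2.07 (adjusted p 3.2e-04 and 6.7e-04). A fit of the 6 overexpressor libraries alone called 265 genes, and the main test called 329 without library 1 of the overexpressor controls and 238 without library 1 of the overexpressor on PEG.

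The genes that responded in the overexpressor were largely those of the wild-type response. Of its 385 rising genes, 343 also rose in wild type, where independent lists would share 46.2, and of its 134 falling genes 105 also fell in wild type, against 22.3. These comparisons share no library, and their fold changes had a Pearson correlation of 0.615 across genes. Of the 58 genes that came on with PEG in wild type, 40 were called higher on PEG in the overexpressor, and the median level of all 58 there was 5.34 FPKM. The number of genes that changed the same way in both genotypes was 448. It was 296 without library 1 of the overexpressor controls and 215 without library 1 of the overexpressor on PEG.

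The test of the difference between the PEG responses called 1873 genes, 873 with a more positive and 1000 with a more negative response in the overexpressor. Of these, 1816 (97%) had a called response in wild type and a smaller or opposite one in the overexpressor. In 2 the response was larger in the overexpressor, and 55 had no called wild-type response. Both tests use the wild-type libraries, which favours the class of smaller or opposite responses. Among the 427 genes at least 4-fold higher on PEG in wild type, 294 had a more negative response in the overexpressor, and the median log2 change of the set was 2.81 in wild type and 1.07 in the overexpressor. Among the 123 genes at least 4-fold lower, 77 had a more positive response, with medians of -2.33 and -0.67. Because these sets were chosen on wild-type libraries that the interaction also uses, their medians overstate the difference. Over all tested genes, the noise-corrected slope of the overexpressor's response on that of wild type was 0.321 (jackknife SE 0.057), where equal responses give 1. The SD of log2 changes, corrected for the spread between libraries, was 0.672 in wild type and 0.271 in the overexpressor. A difference in variance as large was reached by 1 of 100 relabellings of genotype within each medium, the real one included (permutation p 0.01, the smallest these can give). Such relabelling removes every genotype effect, so it does not test equal PEG responses beside a genotype effect.

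**Figure D2:**
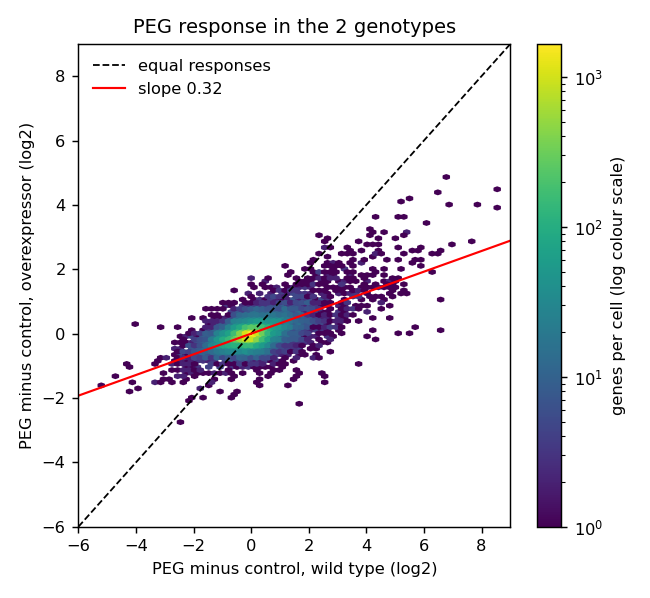
PEG minus control in wild type (x axis, log2) against PEG minus control in the overexpressor (y axis, log2) for 24976 genes, coloured by the number of genes per cell. The dashed line marks equal responses and the red line the noise-corrected slope of 0.321. Most genes with a large wild-type response lie nearer to the x axis than the dashed line.

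By the naming rule, the most negative interactions were in Potri.004G067600.v3.1 and Potri.011G150400.v3.1. The rule leaves out genes whose genotypes overlap on PEG, among them Potri.013G100700.v3.1 and Potri.013G100800.v3.1, with called interactions of -6.52 and -5.56. Potri.004G067600.v3.1 reached 126 ± 58.3 FPKM on PEG in wild type and 2.1 ± 3.05 FPKM in the overexpressor, from 0.232 and 0.049 FPKM on control medium (interaction -5.46, SE 0.774, adjusted p 0.00171). With limma-voom on recovered reads its interaction was -6.05 with an adjusted p of 0.281, and over the alternatives it ran from 9.07e-05 to that value. Potri.011G150400.v3.1 rose in wild type from 0.165 ± 0.124 to 50.7 ± 9.27 FPKM and stood at 18.7 FPKM on both media in the overexpressor (interaction -5.42, SE 0.498, adjusted p 2.03e-04). The most positive interactions were in Potri.014G149700.v3.1 (3.58, SE 0.517, adjusted p 0.00191, with 0.0012 to 0.0567 over the alternatives) and Potri.017G018100.v3.1 (3.36, SE 0.856, adjusted p 0.0349). Potri.014G149700.v3.1 also fell on PEG in the overexpressor (log2 change -1.63, limma adjusted p 0.043). There it went from an already low 4.74 ± 2.77 to 0.676 ± 0.124 FPKM, against 2.31 ± 0.997 in wild type on PEG. Potri.017G018100.v3.1 had 21.3 ± 20 FPKM in wild-type controls, 1.1 ± 1.11 in wild type on PEG, and 7.49 ± 2.61 and 9.66 ± 6.93 in the overexpressor on control medium and PEG. The call of Potri.014G149700.v3.1 was lost with limma-voom (3.19, adjusted p 0.0567), and that of Potri.017G018100.v3.1 with limma-voom (4.63, adjusted p 0.11) and with no filter (3.36, adjusted p 0.0606). The latter call was also lost, with adjusted p from 0.0513 to 0.0887, when library 2 or 3 of the wild-type controls, 1, 2 or 5 of the overexpressor controls, 1 or 3 of wild type on PEG, or 1 or 4 of the overexpressor on PEG was left out. The number of interaction genes was 1240 without library 3 of the wild-type controls, 967 without library 1 and 1136 without library 3 of wild type on PEG.

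On control medium, 3191 genes were higher and 1889 lower in the overexpressor than in wild type, 592 and 283 of them at least 2-fold. The largest rises were in the neighbouring identifiers Potri.013G100700.v3.1, from 0.374 ± 0.18 FPKM in wild type to 99.6 ± 36.6 in the overexpressor, and Potri.013G100800.v3.1, from 0.567 ± 0.52 to 70.2 ± 28.1 FPKM. Their log2 changes were 6.13 (SE 0.404, adjusted p 1.12e-05) and 5.48 (SE 0.417, adjusted p 2.23e-05). Both have a recovered length of 1283 bases, so reads may be shared between near-identical copies and the values of each are uncertain. The largest falls were in Potri.014G149700.v3.1, from 120 ± 35.5 to 4.74 ± 2.77 FPKM (log2 change -4.51, SE 0.366, adjusted p 3.3e-05), and Potri.001G176200.v3.1, from 110 ± 52.9 to 7.81 ± 1.85 FPKM (log2 change -3.57, SE 0.438, adjusted p 3.69e-04). The share of calls that were higher was 62.8% on the FPKM as deposited, 46.1% with median-ratio scaling, 52.7% with upper-quartile scaling and 44% with limma-voom, so which direction holds more genes depends on the scaling. In place of 5080 genes, 3147 were called without library 2 of the wild-type controls and 3325 in a fit of the 6 libraries compared.

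The changes of the overexpressor on control medium ran along the PEG response of wild type. Of the 2994 genes higher on PEG in wild type, 1118 were already higher in the overexpressor on control medium and 72 were lower. Of the 4153 genes lower on PEG, 1177 were already lower and 125 higher. The 4 genes named above were chosen on the same wild-type controls and lay in the direction of the PEG response: Potri.013G100700.v3.1 and Potri.013G100800.v3.1 stood at 136 ± 25.1 and 79.8 ± 18.1 FPKM in wild type on PEG, and Potri.014G149700.v3.1 and Potri.001G176200.v3.1 at 2.31 and 3.32 FPKM. The genes with the largest PEG rises in wild type did not pass the test here, with log2 differences on control medium of 0.22 for Potri.001G391200.v3.1 (adjusted p 0.744) and -0.32 for Potri.007G120400.v3.1 (adjusted p 0.565). Independent lists would share 382.5 rising and 314.1 falling genes. Both comparisons use the wild-type controls. The correlation of fold changes across genes was 0.508, and unchanged groups against shared controls gave 0.501 in simulation. The covariance was 0.16 against 0.02 in simulation, a difference of 0.14. The 3 controls are too few to be divided into sets of at least 2 libraries, so part of the excess in the shared calls may come from the shared controls. Corrected for the shared libraries, the slope of the genotype effect on the wild-type PEG response was 0.31 (jackknife SE 0.041). This slope and that of the overexpressor's PEG response are linked by construction and are not independent results.

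**Figure D3:**
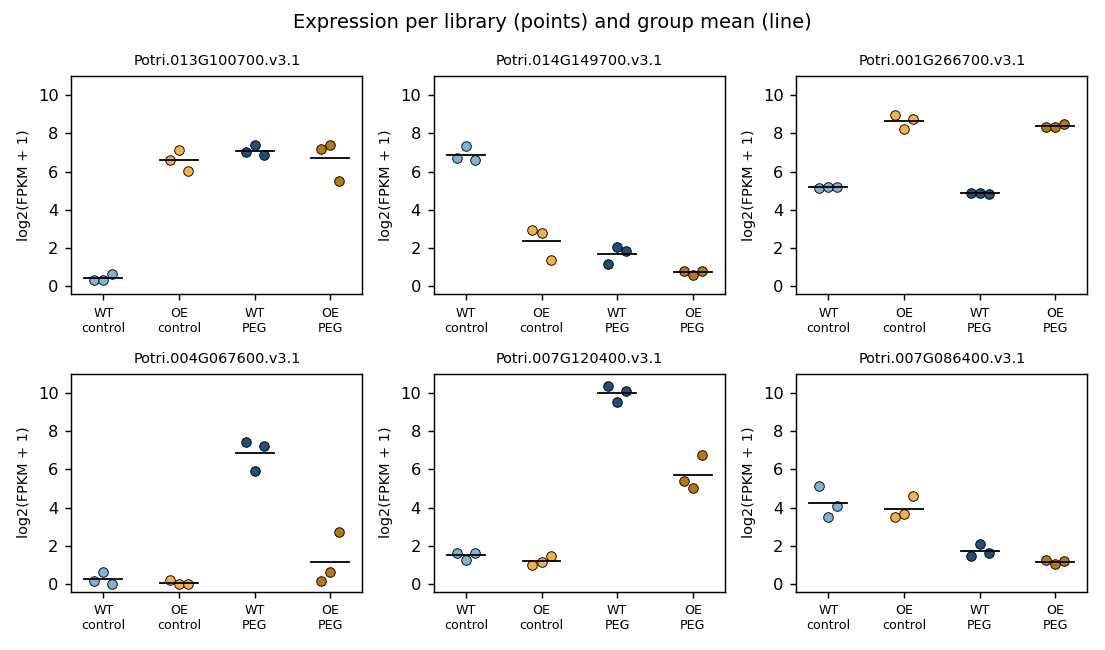
log2(FPKM + 1) of 6 genes in each of the 12 libraries. Points are libraries, coloured by group, and lines are group means of 3 libraries. Potri.013G100700.v3.1 is near 0 in wild-type controls and high in the other groups, Potri.014G149700.v3.1 is high in wild-type controls, Potri.001G266700.v3.1 is high in the overexpressor on both media, Potri.004G067600.v3.1 and Potri.007G120400.v3.1 are highest in wild type on PEG, and Potri.007G086400.v3.1 is lower on PEG in both genotypes.

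On PEG, 2296 genes were higher and 1324 lower in the overexpressor than in wild type. Large differences were mostly reductions, with 103 genes at least 4-fold lower and 7 at least 4-fold higher. Potri.001G266700.v3.1 stood highest, at 331 ± 19.8 FPKM against 28.1 ± 0.331 in wild type (log2 change 3.51, SE 0.143, adjusted p 2.94e-07), followed by Potri.003G215001.v3.1, at 31.9 ± 8.02 against 4.63 ± 2.93 FPKM (log2 change 2.64, SE 0.532, adjusted p 0.00703). The largest reductions were in Potri.004G067600.v3.1 (log2 change -5.67, SE 0.547, adjusted p 8.18e-05) and Potri.011G110300.v3.1, at 8.56 ± 8.39 against 229 ± 97.3 FPKM (log2 change -4.83, SE 0.46, adjusted p 7.66e-05). Of the 2994 genes that PEG raised in wild type, 881 were lower in the overexpressor on PEG, and of the 4153 that it lowered, 1119 were higher. Independent lists would share 158.7 and 381.8. The comparisons share the wild-type PEG libraries: the correlation of fold changes was -0.623 against -0.501 in simulation and the covariance -0.186 against -0.02, and part of the excess in shared calls may come from these libraries. Higher calls made up 63.4% of the total on the FPKM as deposited, 43.9% with median-ratio scaling, 53.2% with upper-quartile scaling and 40.8% with limma-voom. In place of 3620 genes, 1779 were called without library 1 and 1746 without library 3 of wild type on PEG, and 2157 without library 3 of the overexpressor on PEG.

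A smaller set of genes differed between the genotypes in the same direction on both media: 853 were higher and 303 lower in the overexpressor, where independent lists would share 293.3 and 100.1. These genotype comparisons share no library, and their fold changes had a Pearson correlation of only 0.181 across genes. The 853 genes had median log2 changes of 0.6 on control medium and 0.58 on PEG. Potri.001G266700.v3.1 led this set, with 35.5 ± 0.623 FPKM in wild type and 408 ± 100 in the overexpressor on control medium (log2 change 3.46, SE 0.143, adjusted p 3.49e-07). It ranked 1 by p-value in both genotype comparisons, and its interaction of 0.05 had an adjusted p of 0.923. Potri.003G215001.v3.1 came next, with a log2 change of 3.19 (SE 0.532, adjusted p 0.00215) on control medium. Of 77 genes at least 2-fold higher on both media, 12 were higher and 6 lower on PEG in wild type. Whether higher or lower genes prevail in the shared set depends on the scaling: the counts were 587 higher and 401 lower with upper-quartile scaling, 456 and 512 with median-ratio scaling, and 448 and 556 with limma-voom. The shared total of 1156 was 638 without library 1 and 587 without library 3 of wild type on PEG, and 696 without library 3 of the overexpressor on PEG.

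**Figure D4:**
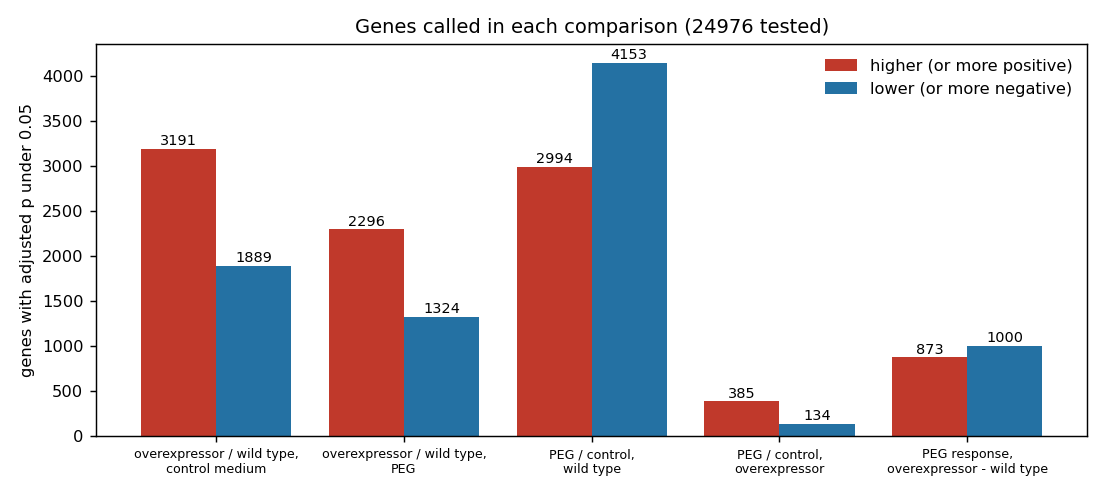
Number of genes with a limma adjusted p under 0.05 in each comparison, higher (red) and lower (blue), of 24976 tested. The PEG response has 7147 calls in wild type and 519 in the overexpressor. In the genotype comparisons the longer bar changes from higher to lower with median-ratio scaling, where 46.1% of calls on control medium and 43.9% on PEG are higher.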

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

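The bound on wild-type control RNA, the excess from libraries not used to choose the genes, the covariance ratio, the test of PEG-treated RNA in the overexpressor controls, the positions of single libraries and the alternative scalings were tests chosen after the result was seen.

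The PEG response differed between the genotypes in 1873 genes by the limma interaction test, which is what marks it for a closer look. Relabelling genotype within each medium gave as many calls in 1 of 100 relabellings drawn from 200 possible, the real one included. The highest of the others drawn gave 487. Such relabelling removes every genotype effect, not only a difference in PEG response. It argues against a random assignment of libraries to genotypes, and cannot test equal PEG responses beside a genotype effect. For the pairwise comparisons, 6 libraries split into 3 and 3 in 10 ways, too few for a share under 0.05. Each split was fitted together with the other 6 libraries, as in the main test. The real split gave 5080, 3620, 7147 and 519 calls for the genotype effect on control medium, the genotype effect on PEG, the PEG effect in wild type and the PEG effect in the overexpressor. The highest other splits gave 5, 0, 1 and 2, and 1 of the 10 splits, the real one, reached the real value in each. Other splits, like the relabellings, put any real difference into the spread within groups. This lowers their calls, so the gap does not measure how far chance was exceeded.

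The first pattern is the smaller PEG response of the overexpressor, with a slope of 0.321 on that of wild type. The slope was at most 0.343 with any of the 12 libraries left out, which argues against a single deviating library, whereas the slopes of at most 0.318 under other scalings decide nothing, because a factor per library moves the response of nearly every gene alike. Wild-type RNA mixed into the overexpressor PEG libraries was not decided by the test planned for it. Over 152 genes higher in the overexpressor on control medium, a median of 54% of the excess remained on PEG. The bootstrap 95% interval of 47.7 to 65.2 is over genes and leaves out the spread between libraries. Moreover, the genes were chosen for that excess. With the excess taken from libraries not used to choose them, the median was 58.8% to 85.6%. To account for the genes at least 4-fold higher on PEG in wild type, such a mixture would need an estimated 61.8% of wild-type control RNA. Choosing these genes on wild-type libraries raises the estimate, and leaving out their control level lowers it. Yet 22 of 9329 genes abundant in wild-type controls lay under 30.9% of that level in all 3 overexpressor PEG libraries (20 such genes had been set as the limit). This argues against a share that large. Potri.014G149700.v3.1 stood at 95.99 to 160.9 FPKM in wild-type controls and at 0.5337 to 0.7587 FPKM in the 3 overexpressor PEG libraries. An admixture of control RNA would carry its share of that level, so this gene argues against more than a small share. An effect of PuC3H35 overexpression on the PEG response and a difference in the growth or development of the roots may each contribute and stay open. An admixture small enough for these values is not excluded, but it would fall short of the estimated 61.8%.

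The second pattern is the shift of the overexpressor on control medium along the wild-type PEG response. Chance values of the shared wild-type controls that are independent between genes do not account for it. The covariance of the fold changes was 7.99 times the one that shared libraries add in such a simulation. A deviation common to many genes or to all 3 controls is not covered by this test. PEG-treated wild-type RNA in the overexpressor controls would raise every gene that PEG turns on, but 46.6% of 58 such genes stayed under 1% of their wild-type PEG level there, while 8 reached 20% or more. The shift was in all 3 libraries, with positions of 0.279 to 0.344 on a scale from wild-type control (0) to wild-type PEG (1), which argues against a single wrong label. The shift was uneven over genes. In the 58 genes that PEG turns on, the median log2 change was 0.308 in overexpressor controls, against 4.706 with PEG in wild type. It was 0.481 against 2.813 in genes at least 4-fold higher on PEG, and -1.06 against -2.33 in genes at least 4-fold lower. These sets were chosen on wild-type controls that both changes share. A partly PEG-like state of unstressed overexpressor roots is a candidate explanation, as a hypothesis found and examined on the same libraries. Growth conditions that differed between the genotypes remain untested.

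The third pattern is the larger number of higher than lower genes in the overexpressor. With median-ratio scaling 46.1% of the calls on control medium were higher, against 62.8% on the deposited FPKM, but that scaling brings the median log2 change from 0.08 to 0.00 by construction, so it decides nothing about the cause. Gene length does not account for it, because the share was 57.7% or more in each of 3 equal classes of genes by length. Whether the excess comes from scaling or from the overexpressor stays open, because these values do not show which scaling reflects RNA amounts per root.

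Single genes with a called interaction, given as overexpressor minus wild-type PEG response in log2, were the following. Potri.013G100700.v3.1 and Potri.013G100800.v3.1 differed by -6.52 and -5.56, with high levels on control medium in the overexpressor. Potri.004G067600.v3.1 differed by -5.46, Potri.011G150400.v3.1 by -5.42 and Potri.011G110300.v3.1 by -4.75. Potri.001G391200.v3.1 differed by -4.67 and Potri.007G120400.v3.1 by -3.95. Potri.014G149700.v3.1, Potri.001G176200.v3.1 and Potri.017G018100.v3.1 differed by 3.58, 3.38 and 3.36.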

How the results depend on the processing

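Median-ratio and upper-quartile scaling, limma-voom on recovered reads, and the fit without library 2 of the wild-type controls and library 4 of the overexpressor on PEG together were chosen after seeing the data. The planned count models with their normalizations were not run because the values are FPKM, and the planned list tests were not run because no identifier had a name. For the named genes, 308 of 324 values kept their direction and their side of the threshold, 16 kept the direction but lost the threshold, and 0 reversed. Most of the 16 were for the interaction of Potri.017G018100.v3.1.

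Counts with a pseudocount of 0.1, no filter, a mean of at least 5 FPKM, or another scaling stayed within 1.5 times the main counts, and limma-voom called 5020, 3217, 6914, 484 and 1713 genes. With limma-voom, 4066 of the 5080 genes called for genotype on control medium and 6366 of the 7147 called for PEG in wild type were shared. Requiring a log2 change of at least 1 as well left 875 genes for genotype on control medium, 726 for genotype on PEG, 2255 for PEG in wild type, 299 for PEG in the overexpressor and 1109 for the interaction, by construction. Fits of the 6 libraries compared gave 3325 genes for genotype on control medium, 3355 for genotype on PEG, 7225 for PEG in wild type and 265 for PEG in the overexpressor, and the cause was not tested.

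With the replicate number as a replicate block in all 12 libraries, calls fell to 3138 and 2174 for genotype on control medium and on PEG, 149 for PEG in the overexpressor and 848 for the interaction. The shared calls fell to 575 for the genotype effects and 132 for the PEG responses. PEG in wild type gave 7230 genes, or 6836 with a replicate block in the 6 wild-type libraries. Potri.007G086400.v3.1 and Potri.001G235500.v3.1 then had adjusted p of 0.0878 and 0.116 for PEG in the overexpressor (0.00133 to 0.0878 and 0.00148 to 0.116 over all alternatives). Deviations of 12 same-numbered pairs correlated at -0.233 to 0.263, with 2 over 0.1. Those of pairs from different groups with different numbers correlated at -0.319 to 0.338. Within the overexpressor only number 1 occurs on both media, and that pair correlated at -0.024. Whether the numbers mark transgenic lines thus cannot be told from these values. If they do, the PEG comparison in the overexpressor, the interaction and the slope in part compare different lines. Some libraries of different groups thus deviated together, for a reason that was not tested. Numbers 4 and 5 each occur in a single library, in the overexpressor on PEG and in the overexpressor controls. The replicate block fits such a library exactly, so it adds nothing to the comparisons. Each overexpressor group was thus compared on 2 libraries, while the wild-type groups lost none. The lower counts are all for comparisons with the overexpressor. How much of the fall comes from this loss of libraries was not tested.

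Leaving out each library in turn gave 3147 to 4650 genes for genotype on control medium, 1746 to 3181 for genotype on PEG, 5266 to 6655 for PEG in wild type, 238 to 459 for PEG in the overexpressor and 967 to 2076 for the interaction. Shared calls ranged from 587 to 1077 for the genotype effects and 215 to 498 for the PEG responses, and the slope from 0.288 to 0.343. The lowest values came without library 2 of the wild-type controls (3147), library 3 of wild type on PEG (1746, 587), library 1 of wild type on PEG (5266, 967) and library 1 of the overexpressor on PEG (238, 215, 0.288). In simulated data for genotype on control medium, 17.9% of 1.5-fold changes were recovered, but few genes were changed there (118 calls), so the adjusted p was stricter than in the data, and the median absolute log2 change of the 5080 called genes was 0.60.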

Other observations

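The tests of adjacent identifiers and the fit without 2 libraries were chosen after the result was seen.

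Some genes had a genotype difference that turned over between the media. In the overexpressor, 126 genes were higher on control medium and lower on PEG, with median levels of 1.85 FPKM in wild-type controls, 5.48 in overexpressor controls, 15.1 in wild type on PEG and 6.73 in the overexpressor on PEG. The converse held for 77 genes, with medians of 31.6, 17.6, 9.36 and 15.3 FPKM in the same order. All 126 were called higher on PEG in wild type, and 76 of the 77 were called lower. The choice of the genes makes this likely, because a genotype effect that turns over on the same libraries favours a wild-type change of that direction. Independent lists would share 169.2 and 173.7 genes, so turning over was not more frequent than chance overlap of the genotype effects, which themselves share no library.

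A set of 66 genes was called for PEG in the overexpressor and not in wild type, 40 higher and 26 lower. The difference between the genotypes was itself called for 11 of them with a more positive and 7 with a more negative response in the overexpressor, so for the others a response confined to the overexpressor was not shown.

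Called genes tended to have called neighbours. Of 18109 pairs of adjacent identifiers with both genes tested, 1081 were called in the same direction for PEG in wild type, against a mean of 761.5 and a highest value of 882 in 1000 shuffles of the calls, a ratio of 1.42 (permutation p 0.001, the smallest these can give). For changes of at least 4-fold it was 69 pairs against 5.7. In the overexpressor 41 pairs were called for PEG against 4.7. As a hypothesis, neighbouring genes may respond together, because they are duplicated copies or share a region. Reads shared between near-identical copies would give the same excess, and were not tested, since no sequences were used here.

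Library 2 of the wild-type controls and library 4 of the overexpressor on PEG lay at the low end of the third principal component, at -22.5 and -43.2. Without both, 3905, 3351, 6585, 541 and 1264 genes were called for genotype on control medium, genotype on PEG, PEG in wild type, PEG in the overexpressor and the interaction. Shared calls were 986 for the genotype effects and 481 for the PEG responses, and the slope was 0.347.

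No chromosome, as read from the identifiers, stood apart. Over 19 chromosomes, the median log2 change between genotypes ran from 0.06 to 0.11 on control medium and from 0.05 to 0.10 on PEG.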
